A study of Mus musculus with 8 samples.

How the data were processed

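RNA from 8 mouse kidney samples was sequenced, 5 labelled Sglt2Cre DOCA and 3 labelled Arhgef11Sglt2 DOCA. Per the labels' protocols, poly(A) RNA was made into stranded libraries with a TruSeq kit, the samples were pooled into 1 sequencing library pool, and paired-end reads were obtained on a NextSeq instrument. Per the submitters' processing notes, Salmon 1.10.0, DESeq2 and the genome build GRCm39 were used; the DESeq2 version, the annotation and the filter on genes are not given in the sources used here.

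The deposited table holds log2 values on a variance-stabilized scale for 15948 genes, although its name speaks of counts. This was read from the values: they are not whole numbers, all 8 columns share a minimum of 8.1275 (279.7 on the linear scale), and that minimum is the value of a zero count. The closed form of the variance-stabilizing transformation was inverted from that minimum, which gives normalized counts. In each library, low values so obtained piled up at multiples of 1 step: of values up to 5 steps, 39.0% lay within 0.02 steps of a whole number, against 4% by chance. Most low values did not, so read counts were not recovered and no count model was used. The size of the step gives an estimated depth per library. The scale compresses differences of low genes (the median gene had 842.6 normalized counts), so folds are ratios of group means of back-transformed normalized counts, while tests, log2 differences and standard errors are on the deposited scale.

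The plan, fixed before the data were examined, was a quasi-likelihood count model. Because the file holds log2 values, limma was used in its place (limma 3.58.1 in R 4.3.3): a linear model with group as its only term, on all 8 libraries and all listed genes, with moderated variances that follow the mean, and Benjamini-Hochberg adjustment over 15948 genes at 0.05. The model has 6 residual degrees of freedom. Arhgef11 was also tested with a two-sided exact permutation test over the 56 splits. Gene symbols came from a reference gene table and matched 15902 identifiers (99.71%); no coordinates are given because that table is of another build.

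The 50 gene lists (645 entries, 631 measured) were tested with camera at a preset correlation of 0.01, requiring at least 3 measured members, and again with an estimated correlation and with fry. Named genes followed a rule fixed before the data were examined: Arhgef11 and Slc5a2; the 10 higher and 10 lower genes with the largest log2 difference among those past the threshold with no overlap between groups and a mean of at least 1 CPM; up to 4 members with the smallest p of each list described; and a fixed panel of kidney genes. A gene and a list that fall under these rules are not reported here. Genes with a model name only (9 of the called genes) were counted but not named. Lox, Mme, Abcc3, Prlr and Slc7a12 and the genes named only with the lists written later are outside that rule and were chosen after their values were seen.

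The main procedure was tested on simulated values for the 15948 genes with 200 changed. At a log2 change of 0.5 it recovered 75.5% with 5.03% false calls, and at a log2 change of 1 it recovered 99.5% with 4.79% false calls. In a simulation with 1 list shifted by 0.3, camera called 1 list. The simulated noise was independent between genes. In the data the estimated correlation within the lists camera called ran from -0.00128 (p53 targets) to 0.768 (cell cycle). The simulations therefore do not show how often false calls arise when genes are correlated. Genes in families of near-identical copies share reads and are uncertain. Alternatives, whose effect is given with the closing observations, covered the filter, blocks for replicate number and for library number range, variance shrinkage, sample weights, pseudocounts of 1 and 10 on the log scale, scaling, the threshold, and each library left out in turn. The library names held numbers from 2244 to 2263 (control replicates 1, 2 and 3, Arhgef11Sglt2 replicates 1 and 2) and from 2287 to 2299 (control replicates 4 and 5, Arhgef11Sglt2 replicate 3). Whether these ranges are separate cohorts is not stated.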

Results

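Messenger RNA was sequenced from 8 mouse kidney samples of a study on Arhgef11, high blood pressure and kidney injury. Arhgef11 encodes a guanine nucleotide exchange factor. The labels named 5 samples Sglt2Cre DOCA (the control group here) and 3 samples Arhgef11Sglt2 DOCA. Sglt2 (gene Slc5a2) is the glucose transporter of the early proximal tubule, and the study's title names a knockout specific to the proximal tubule. DOCA, in hypertension research, is the mineralocorticoid deoxycorticosterone acetate, given here to both groups, so no comparison with untreated kidneys was analysed here. The labels did not state that the samples came from separate animals, so the p-values measure the spread between these samples, part of which may be technical. Normalized counts per library summed to between 43040000 and 46680000 over 15948 genes. The depth before normalization, estimated from the spacing of the low values, was 33000000 to 59700000 reads in the control libraries and 51300000 to 58000000 reads in the Arhgef11Sglt2 libraries. The most abundant transcript in every library was mt-Co1, with 3.61% to 4.55% of normalized counts.

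The groups were separated along the first principal component, which held 44.4% of the variance. The control libraries lay between -13.1 and -5.70 on it, and the Arhgef11Sglt2 libraries at 4.69 (replicate 1), 14 (replicate 2) and 31.3 (replicate 3). Replicate 1 of the Arhgef11Sglt2 group thus lay nearest to the controls, and on the second component (16.4% of the variance) it had the lowest value, -15.4.

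**Figure D1:**
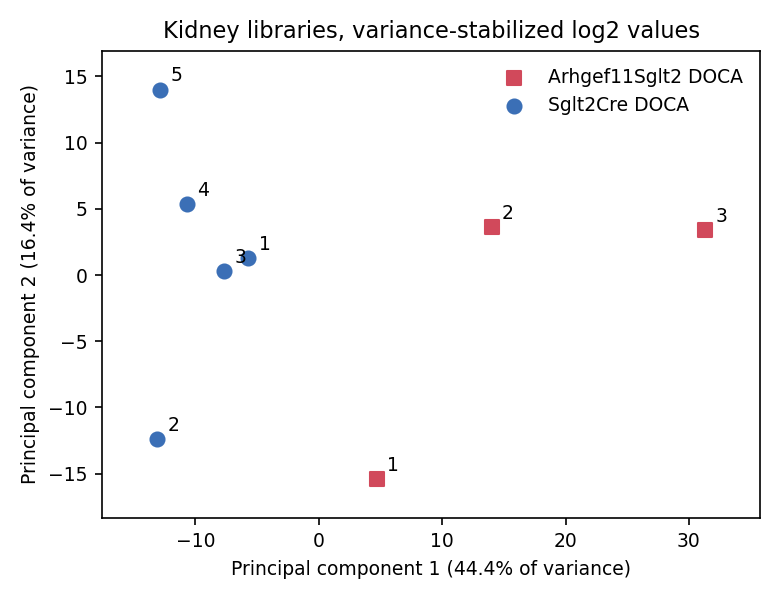
Principal components of the variance-stabilized log2 values of 15948 genes; each point is 1 library, labelled with its replicate number, with circles for Sglt2Cre DOCA and squares for Arhgef11Sglt2 DOCA. The 3 Arhgef11Sglt2 libraries lie at 4.69, 14 and 31.3 on the first component, to the right of all 5 control libraries.

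The first question was whether the targeted transcript was lower in the kidneys labelled Arhgef11Sglt2. Arhgef11 (ENSMUSG00000041977) had 3679.5 ± 161.6 normalized counts in the control libraries (SD, n = 5) and 3587 ± 564 in the Arhgef11Sglt2 libraries (SD, n = 3). The log2 difference was -0.04 (SE 0.09, 95% interval -0.24 to 0.16), with an adjusted p of 0.834 in limma. A two-sided exact permutation test over the 56 splits of the libraries gave an unadjusted p of 0.732. The smallest p possible in that test is 0.0179. Replicates 1, 2 and 3 of the Arhgef11Sglt2 group had 2935, 3919 and 3905 normalized counts, so only replicate 1 was below every control library (3479 to 3928). The whole-gene value in whole kidney therefore did not check the labels. It cannot show whether part of the transcript was deleted, nor a loss limited to proximal tubule cells, and every direction below refers to libraries as labelled. Slc5a2 had 18544 ± 2557 normalized counts in the controls and 14289 ± 3563 in the Arhgef11Sglt2 libraries (log2 difference -0.38, SE 0.16, limma adjusted p = 0.214; exact permutation p = 0.0536). The related exchange factors Arhgef12 (1.06-fold, limma adjusted p = 0.696) and Arhgef1 (1.18-fold, limma adjusted p = 0.263) did not pass the threshold.

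The second question was which genes differed between the groups. Kidneys labelled Arhgef11Sglt2 had higher transcripts of the fibrinogen chains Fga, Fgb and Fgg, of the lipid droplet gene Plin2 and of the tubule injury markers Lcn2 and Krt20. They had lower transcripts of the late proximal tubule transporters Slc7a13 and Slc22a30, of the cholesterol synthesis enzyme Idi1 and of the plasma cell genes Igkc and Jchain. In limma, 354 of the 15948 genes passed a Benjamini-Hochberg adjusted p of 0.05, 100 higher and 254 lower. When the libraries were scaled to equal totals the split was 149 higher and 178 lower, so the share of higher calls went from 28.2% to 45.6%. Of the 354 genes, 353 had no overlap between the groups of libraries, as had 2286 (14.3%) of all genes, where chance gives 3.57%. Among the called genes, 42 were more than 2-fold higher and 94 more than 2-fold lower.

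The count depended on single libraries. It was 1334 without replicate 1 of the Arhgef11Sglt2 group and 45 without replicate 3. It was 187, 135, 24 and 76 without control replicates 1, 3, 4 and 5.

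The 9 named genes that were higher included genes of lipid metabolism. Cyp4a14, a fatty acid hydroxylase, was 5.27-fold higher (8075 ± 4958 against 42577 ± 21778 normalized counts, limma adjusted p = 0.0466). Replicate 1 of the Arhgef11Sglt2 group (18321) lay close to control replicate 1 (15758), while replicates 2 and 3 of that group had 60449 and 48959. Plin2, a coat protein of lipid droplets, was 4.51-fold higher (3352 ± 557 against 15101 ± 11805, limma adjusted p = 0.0389) and 2.47-fold higher without replicate 3 of the Arhgef11Sglt2 group. Angptl4, a secreted inhibitor of lipoprotein lipase, was 3.36-fold higher (limma adjusted p = 0.0389). The fibrinogen chain genes Fga, Fgb and Fgg were 4.50-fold, 4.35-fold and 4.16-fold higher, with limma adjusted p of 0.022, 0.0482 and 0.0467. For Fgb and Fgg, replicate 3 of the Arhgef11Sglt2 group (1330 and 7145 normalized counts) lay close to control replicate 3 (1216 and 6508). Replicates 1 and 2 of the Arhgef11Sglt2 group had 3511 and 4069 for Fgb, and 19479 and 18772 for Fgg. Krt20, a keratin of injured tubule, was 7.47-fold higher (169.7 ± 95.02 against 1268 ± 1051 normalized counts, limma adjusted p = 0.0458), and 3.90-fold higher without replicate 1 of the Arhgef11Sglt2 group. Lcn2, a secreted marker of tubule injury, was 3.14-fold higher (1976 ± 480 against 6195 ± 1607, limma adjusted p = 0.0154). Hmcn1, an extracellular matrix protein, was 7.13-fold higher (636.7 ± 843.0 against 4536 ± 1360 normalized counts, limma adjusted p = 0.0331). Control replicate 3 had 2125, and without it the fold was 17.1.

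The 10 named genes that were lower included transporters and enzymes of the late proximal tubule. Slc7a13, an amino acid transporter of its last segment, was 7.22-fold lower (17107 ± 9655 in the controls against 2369 ± 1262 normalized counts, limma adjusted p = 0.037). Acsm3, a medium-chain acyl-CoA synthetase, was 9.99-fold lower (limma adjusted p = 0.0458), and Cyp2j13, a cytochrome P450, 5.27-fold lower (limma adjusted p = 0.0338). The organic anion transporter genes Slc22a30 and Slc22a28 were 4.29-fold and 4.08-fold lower, with limma adjusted p of 0.0176 and 0.0131. Their values are uncertain because this family holds near-identical copies that share reads, which also applies to Cyp4a14 and to Ces1f, a carboxylesterase that was 3.05-fold lower (limma adjusted p = 0.037). Inmt, an amine methyltransferase, was 4.97-fold lower and Pzp, a protease inhibitor, 10.1-fold lower, with limma adjusted p of 0.0389 and 0.02. The immunoglobulin kappa constant gene Igkc was 5.81-fold lower and Jchain, the joining chain of IgA and IgM, 6.58-fold lower, with limma adjusted p of 0.0422 and 0.0401. Single libraries moved the size of some of these differences. Without replicate 1 of the Arhgef11Sglt2 group Acsm3 was 21.5-fold and Pzp 19.3-fold lower. Without replicate 2 of that group Igkc was 9.96-fold and Jchain 11.4-fold lower. Control replicate 2 nearly met replicate 2 of that group for Igkc (2083 against 2068 normalized counts) and Jchain (700 against 665). For Acsm3, control replicate 1 (1786) lay close to replicate 1 of the Arhgef11Sglt2 group (1342).

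**Figure D2:**
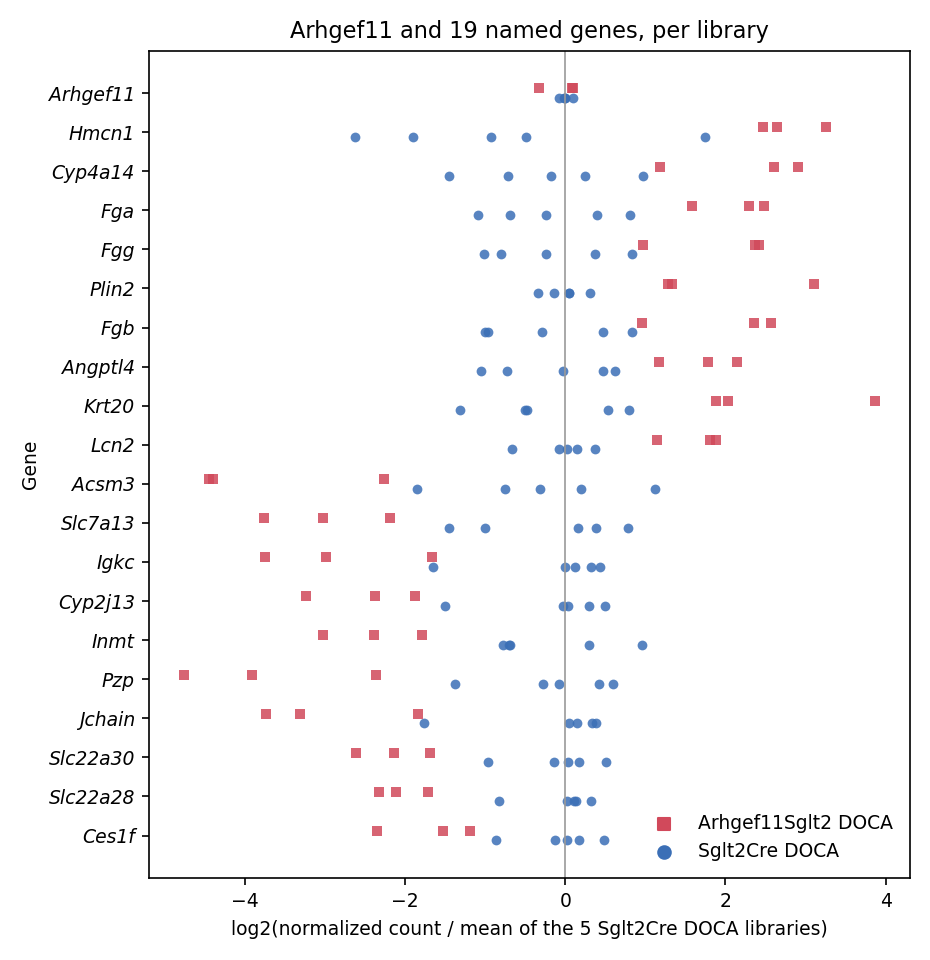
Normalized count of Arhgef11 and of 19 named genes in each library, on a log2 axis relative to the mean of the 5 control libraries; circles are Sglt2Cre DOCA and squares Arhgef11Sglt2 DOCA. Arhgef11 lies near 0 in both groups, while the other genes do not overlap between the groups.

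The third question was whether genes of known pathways and cell types moved together. Of 50 lists fixed before the data were examined, camera with a preset correlation of 0.01 called 19, 10 higher and 9 lower. None of these calls held with an estimated correlation between genes, where the lowest adjusted p was 0.454, and 14 of the 56 splits of the libraries called 19 or more lists. The list results below are therefore given as counts of members and as values per list. In an exact permutation test of each list's mean over the 56 splits, 14 lists had a p under 0.05, and the lowest was 0.0179, the smallest possible, which became 0.0992 after Benjamini-Hochberg adjustment over the 50 lists. Some lists that camera called had a higher exact permutation p. It was 0.0714 for heat shock, 0.196 for the early proximal tubule and 0.321 for both cell cycle and cytosolic ribosomal proteins. For cytokines, chemokines and adhesion molecules it was 0.357, and for interferon response 0.446.

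Of the 19 cholesterol synthesis genes measured, 8 were lower in limma over all genes and 15 when adjusted over the list alone, and all 19 had a negative difference. The camera adjusted p was 2.46e-12, and the adjusted p was 0.454 with an estimated correlation. Idi1 was 2.96-fold lower (4331 ± 690 in the controls against 1461 ± 711 normalized counts, limma adjusted p = 0.0175), and Cyp51 was 1.81-fold lower (limma adjusted p = 0.02). Nsdhl and Dhcr7 were 1.59-fold and 1.61-fold lower.

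Of the 20 fatty acid oxidation genes, 3 were higher in limma over all genes, and 10 were higher and 1 lower when adjusted over the list alone. The 3 included Cyp4a14 and Slc25a20, the mitochondrial carnitine carrier (1.67-fold, limma adjusted p = 0.0425). Pdk4, a kinase that restrains pyruvate oxidation, had 1366 ± 280 against 10473 ± 10136 normalized counts and a limma adjusted p of 0.0504; replicate 3 of the Arhgef11Sglt2 group had 21964. The camera adjusted p was 1.36e-05 (adjusted p = 0.558 with an estimated correlation). The mean of the list relative to the controls was 0.18 in replicate 1 of the Arhgef11Sglt2 group, 1.01 in replicate 2 and 0.97 in replicate 3, and the median log2 difference of 0.36 became 0.59 without replicate 1. Genes of oxidative phosphorylation encoded in the nucleus had a median log2 difference of -0.20, with all 20 members negative. Only Ndufs1, a complex I subunit, passed in limma (1.43-fold lower, adjusted p = 0.0224), and 4 passed when adjusted over the list alone. Camera gave an adjusted p of 1.87e-05 (adjusted p = 0.558 with an estimated correlation).

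Genes of the last proximal tubule segment had a median log2 difference of -1.02. Of 9 measured, 4 were lower in limma over all genes and 5 when adjusted over the list alone: besides Slc7a13 and Slc22a30, the aminoacylase Acy3 (2.75-fold, limma adjusted p = 0.022) and the brush border protease subunit Mep1b (2.38-fold, limma adjusted p = 0.023) passed over all genes. Camera gave an adjusted p of 8.74e-05 (adjusted p = 0.454 with an estimated correlation). The male-biased kidney genes, 2 of which are also in that list, had a median of -1.32; 3 of 10 were lower over all genes and 7 when adjusted over the list alone. The abundant androgen-regulated transcript Kap had 263535 ± 101967 normalized counts in the controls and 71446 ± 45372 in the Arhgef11Sglt2 libraries (limma adjusted p = 0.0587). Control replicate 1 lay with the other group here: its mean over the list relative to the controls was -0.84, beside -0.92 in replicate 1 of the Arhgef11Sglt2 group and -0.05 to 0.65 in the other controls, and the same libraries had 113909 and 120196 normalized counts of Kap. For this list camera gave an adjusted p of 5.82e-05 (adjusted p = 0.454 with an estimated correlation). Markers of the early proximal tubule had a median of -0.30, and 2 of 17 were lower over all genes, 3 when adjusted over the list alone. These were led by the endocytic receptor Lrp2 (1.63-fold) and the phosphate cotransporter Slc34a1 (1.62-fold), with limma adjusted p of 0.0462 and 0.0491. The camera adjusted p was 0.00593 (adjusted p = 0.753 with an estimated correlation), and it was 0.434 without replicate 1 of the Arhgef11Sglt2 group. The mean of this list relative to the controls was -0.53, 0.17 and -0.42 in replicates 1, 2 and 3 of that group. The controls ran from -0.09 to 0.09, so replicate 2 lay above all of them. Of the 17 members, 5 had a positive difference. Thick ascending limb markers had a median of -0.40, with 1 of 9 lower over all genes, the tight junction gene Cldn10 (1.52-fold, limma adjusted p = 0.0476), and 5 when adjusted over the list alone. Camera gave an adjusted p of 0.00078 (adjusted p = 0.454 with an estimated correlation).

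Tubule injury genes had a median log2 difference of 0.35. Of 19 measured, 3 were higher in limma over all genes, Krt20, Lcn2 and the stress-induced growth factor Gdf15 (2.82-fold, limma adjusted p = 0.0401), and 7 when adjusted over the list alone. Havcr1, the injury marker KIM-1, had 3212 ± 1052 normalized counts in the controls and 8028 ± 7604 in the Arhgef11Sglt2 libraries (limma adjusted p = 0.299). Replicate 1 of that group had 16766 and the other libraries of the group 4401 and 2916. The camera adjusted p was 1.36e-05 (adjusted p = 0.491 with an estimated correlation), and it was 0.0528 without that replicate. Leaving out replicate 1, 2 or 3 of that group gave the list a median of 0.19, 0.58 or 0.57. Of 20 immediate early genes, 3 were higher over all genes and 12 when adjusted over the list alone: Myc (2.42-fold), Ier3 (2.03-fold) and Zfp36 (1.34-fold), with limma adjusted p of 0.0417, 0.0387 and 0.0467. Camera gave an adjusted p of 2.08e-08 for these (adjusted p = 0.454 with an estimated correlation). None of the 12 NRF2 targets passed over all genes, and their median of 0.44 became 0.285 without replicate 3 of the Arhgef11Sglt2 group; when adjusted over the list alone, 6 were higher and 1 lower. The camera adjusted p was 0.00166 (adjusted p = 0.454 with an estimated correlation).

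Among immune cells, 2 of 9 B and plasma cell genes were lower in limma over all genes, Igkc and Jchain, and 3 when adjusted over the list alone (camera adjusted p = 0.0135; adjusted p = 0.454 with an estimated correlation). Without replicate 1 of the Arhgef11Sglt2 group the camera adjusted p was 0.0942, and with a replicate block it was 0.0545. The size of the difference depended on the setting: the median of -0.12 was -0.068 without control replicate 2, -0.41 as log2(normalized count + 1) and -1.03 under a stricter filter on low values. Of 5 neutrophil genes, Retnlg was higher over all genes (6.60 ± 6.56 against 33.9 ± 6.91 normalized counts, 5.13-fold and 8.87-fold without control replicate 2, limma adjusted p = 0.0467) and 4 were higher when adjusted over the list alone. Camera gave 0.00166 as the adjusted p (adjusted p = 0.454 with an estimated correlation). Of 19 genes of cytokines, chemokines and adhesion molecules, only the neutrophil chemoattractant Cxcl1 was higher, over all genes and over the list alone (3.67-fold, limma adjusted p = 0.0484). Its list had a camera adjusted p of 0.0138 (adjusted p = 0.753 with an estimated correlation), 0.8 without replicate 1 of the Arhgef11Sglt2 group, where its median turned from 0.078 to -0.017, and 0.0766 without control replicate 2, where its median was 0.032. Leaving out replicate 2 or 3 of the Arhgef11Sglt2 group raised the median to 0.13 or 0.14. No macrophage gene passed (13 measured, median -0.05, camera adjusted p = 0.966), but the libraries went apart: the mean of the list relative to the controls was 0.46, -0.06 and -0.50 in replicates 1, 2 and 3 of the Arhgef11Sglt2 group, against -0.14 to 0.11 in the controls. Adgre1 had 823.6 ± 200.4 against 623.6 ± 348.4 normalized counts.

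The remaining lists that camera called held no member past the threshold over all genes. They were heat shock (median log2 difference -0.34, adjusted p = 0.00166), cell cycle (-0.25, adjusted p = 0.0101), cytosolic ribosomal proteins (0.12, adjusted p = 0.00884), hypoxia (0.34, adjusted p = 0.025), interferon response (0.08, adjusted p = 0.0483) and p53 targets (0.10, adjusted p = 0.0483). With an estimated correlation the adjusted p was 0.558 for heat shock, 0.454 for p53 targets and 0.753 for the other 4. When adjusted over the list alone, 7 heat shock genes were lower, 1 hypoxia gene was lower and 1 p53 target was higher. The hypoxia gene was Vegfa, whose direction was opposite to its list's median. Single libraries ended calls of several of these lists in camera. Without replicate 3 of the Arhgef11Sglt2 group hypoxia had a median of 0.079 (adjusted p = 0.352) and cell cycle -0.17 (0.128). Without replicate 1 of that group interferon response had 0.019 (0.736) and p53 targets 0.14 (0.143). Other omissions took medians further from 0: hypoxia to 0.55 without replicate 2 of that group, cell cycle to -0.38 without replicate 1, and interferon response to 0.19 without replicate 3 and 0.14 without control replicate 4. Without replicate 2 of that group interferon response had an adjusted p of 0.0741 and cell cycle 0.0628. Without control replicate 2 interferon response had a median of 0.038 (adjusted p = 0.236), cell cycle -0.16 (0.198) and p53 targets 0.075 (0.0638). The p53 call also ended without control replicate 1 (0.0529), 3 (0.0863) or 5 (0.0747). Without replicate 3 of the Arhgef11Sglt2 group the p53 median was 0.057 (0.0496). The ribosomal protein call ended without control replicate 5, where its median was 0.074 (0.0796).

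Several lists close to the study's subject were not called by camera. The SRF and YAP targets had no member past the threshold over all genes (16 measured, adjusted p = 0.796). Extracellular matrix and fibroblast genes had 1 of 17 higher, the collagen cross-linking enzyme Lox (adjusted p of the list = 0.603). Col1a1 had 7108 ± 729 against 6416 ± 4732 normalized counts (limma adjusted p = 0.582), Col3a1 0.91-fold (0.598) and Fn1 0.79-fold (0.406). Here too the libraries went apart. The mean of the list relative to the controls was 0.38, -0.10 and -0.73 in replicates 1, 2 and 3 of the Arhgef11Sglt2 group. It was -0.11 to 0.16 in the controls. Col1a1 had 11404, 5854 and 1989 normalized counts in these replicates. Sodium transport genes had 1 of 20 lower, Slc34a1 (camera adjusted p of the list = 0.448). When adjusted over the list alone, 2 were higher and 2 lower. Slc12a1 was 1.62-fold lower (63494 ± 9758 in the controls against 39179 ± 6516 normalized counts, limma adjusted p = 0.0536). Slc9a3 was at 0.96-fold, Slc12a3 at 0.85-fold, Scnn1a at 1.003-fold and Sgk1 at 1.36-fold, none past the threshold. The renin-angiotensin-aldosterone list had a median log2 difference of -0.24 and an adjusted p of 0.0906. Of its 10 measured members, the peptidase gene Mme was lower over all genes (1.52-fold, limma adjusted p = 0.0264), and 5 were lower and 1 higher when adjusted over the list alone. Agt had 2728 ± 536 against 4577 ± 973 normalized counts (limma adjusted p = 0.0617). Ren1 had 521.1 ± 354.4 against 1233 ± 1326 (limma adjusted p = 0.463; 0.91-fold without replicate 3 of the Arhgef11Sglt2 group), Spp1 1.89-fold (0.212) and Ccl2 1.07-fold (0.983). Podocyte (camera adjusted p = 0.293), endothelium (0.985) and smooth muscle (0.205) markers were not called either.

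**Figure D3:**
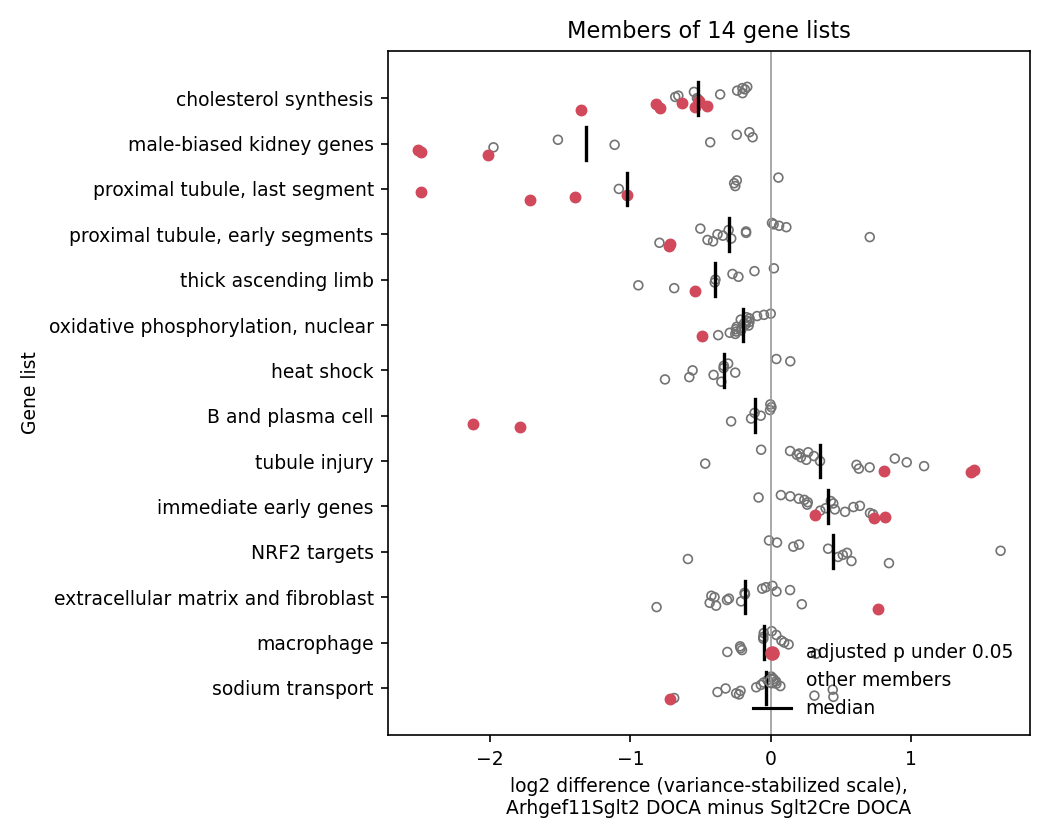
Log2 difference (Arhgef11Sglt2 DOCA minus Sglt2Cre DOCA, variance-stabilized scale) of each measured member of 14 lists fixed before the data were examined; filled points passed an adjusted p of 0.05 over all genes in limma, open points did not, and bars are medians. The medians are -0.52 for cholesterol synthesis, -1.02 for the last proximal tubule segment and 0.35 for tubule injury.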

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

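The tests of the gene count over splits, of exchanged libraries, of transcript from other cells, of tissue composition, of sex, of androgen response and of food intake were chosen only after the results they bear on were seen. Those of the list count over splits and of time of day were written before, and the bound for a single wrong label was set before the held-out position was computed but after the counts with a library moved were seen. For the number of genes that differed, chance splits of the samples are argued against, though not excluded. Only 1 of the 56 splits, the labelled one, called as many as 354 genes, and the highest of the others called 3. The smallest p that 56 splits can give is 0.0179, and this test was chosen after the count was seen. The number of lists gives no argument against chance, since 14 of the 56 splits called 19 or more lists, and the highest of the others called 25.

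Arhgef11 was not lower in the libraries labelled Arhgef11Sglt2. A library of each group exchanged is argued against, because none of the 15 one-for-one exchanges called more than 2 genes. A single library labelled wrongly was weighed for replicate 1 of the Arhgef11Sglt2 group, since moving it to the controls called 797 genes, more than the 354 of the labelled split, while moving any other library called at most 95. Such a label could not by itself explain why Arhgef11 was not lower. The Arhgef11 log2 difference was 0.079 (limma adjusted p = 0.469) without replicate 1 of that group. Its held-out position, over genes called without it, was 0.295 (0 at the control mean, 1 at the mean of the other libraries of its group), above the highest held-out control (0.186) by slightly more than the SD of the controls (0.0843), the bound set beforehand. That bound was too weak to decide, because another measure lay within the range of the held-out controls. The library had 74.6% of these genes on the side of its group, against 46.5% to 79.5% in those controls. The top of that range was control replicate 1 alone, with the next control at 65%. That control also had the highest position, with the next at 0.0828. The share of these genes past the midpoint went the other way, at 33.1% against 1.74% to 14.5% in the held-out controls. Each held-out control was placed over more genes (344 to 1218) than were called with only that control left out (24 to 284). As the measures differ, a wrong label of this library cannot be told apart from a weaker group difference in this library. Its Arhgef11 value was the lowest of the 8 libraries and its difference was not weaker throughout. Its mean over the tubule injury list was 1.01 (0.22 and 0.33 in its group, -0.26 to 0.11 in the controls) and Lcn2 was 7302 (at most 2553 in the controls). In the lists that camera called, its mean lay outside the range of the controls on its group's side, except for heat shock, cell cycle and cytosolic ribosomal proteins. These lists were called with this library in that group and were compared after the values were seen, so they do not exclude a wrong label. Transcript from other kidney cells, or from an allele without the deleted part that is still counted, cannot be told apart from an unchanged gene, because a gene-level difference of -0.0411 does not place reads within the gene.

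Of the male-biased genes 3 of 10, and of the last proximal tubule segment 4 of 9, were lower in limma, with a median log2 difference of -1.08 over the 17 genes of both lists; neither list was called with an estimated correlation (adjusted p = 0.454 for each). A loss of all proximal tubule segments alike from the tissue sampled is argued against: the median of early-segment genes was higher than that of the pattern by 0.782, more than the median absolute deviation of the early-segment genes (0.202), and thick ascending limb markers had a median of -0.40, not above 0. These medians cannot tell tissue with less of the last segment in particular from lower transcripts within it. The libraries also differed. The means of the early-segment and last-segment lists were 0.17 and -1.09 in replicate 2 of the Arhgef11Sglt2 group, and -0.42 and -1.07 in replicate 3. In replicate 1 they were closer, at -0.53 and -0.64, so the argument is weaker for that library. A sex difference between the groups is argued against, because the largest difference of a Y-linked gene was 0.233. A weaker androgen response may contribute but cannot be told apart, since the 4 female-biased genes went both ways: 2 were higher (Cyp4a14 and Abcc3), while Prlr (log2 difference -0.74) and Slc7a12 (-0.37) went against it and Prlr was lower when adjusted over the list alone. The knockout itself remains an untested biological explanation.

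Of the fatty acid oxidation genes 3 of 20 were higher, and of the cholesterol synthesis genes 8 of 19 were lower, in limma; neither list was called with an estimated correlation (adjusted p = 0.558 and 0.454). A different time of day at collection between the groups as a whole is argued against, because clock genes of opposite phases moved apart by only 0.192 on the log2 scale. That value compares group means, so collection times that differed within a group were not tested. Lower food intake before collection might give this pattern but cannot be told apart from an effect of the genotype: other PPAR alpha targets had a median log2 difference of 0.667, but these were listed after the data were seen, and the gluconeogenesis list, fixed before, was not called (camera adjusted p = 0.309). Food intake is not in the labels.

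In the 5 control libraries, 9 of the 100 named genes had 1 library far from the others by Dixon's criterion, where chance flags about 1 in 20, or 5. Control replicate 1 was the outlying library for 4 of them. It was lowest for Cyp2j13 (2914 normalized counts, next 8087), Slc22a28 (3181, next 5715), Lrp2 (100570, next 116321) and Dhcr7 (920.8, next 1082). In each of these 4 genes it deviated in the direction of the Arhgef11Sglt2 libraries. Control replicate 2 was lowest for Igkc (2083, next 6508), Jchain (699.9, next 2451) and Ifit2 (861.8, next 1344). It was highest for S100a9 (150.4, next 39.3) and Zmat3 (1850, next 1669). In all of these but Ifit2 it also deviated in the direction of the Arhgef11Sglt2 libraries.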

How the results depend on the processing

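The alternatives of robust shrinkage, no variance trend, sample weights, pseudocounts and scaling were chosen only after the data were seen. The signs of the 354 genes do not measure stability, because 353 of them have no overlap between the groups (340 were tested under the stricter filter). The count was 0 with a replicate block, where 2166 genes had an unadjusted p under 0.05 in limma (3367 without the block) and 23 lists were called; this fit spends most of its degrees of freedom on the block. Deviations of same-numbered samples correlated at -0.175, -0.088 and -0.00676, and none of the 3 Arhgef11Sglt2 samples correlated best with its own number, so the numbers do not pair the samples. The count was 874 with sample quality weights (39.4% higher) and 1038 at an adjusted p under 0.1. Leaving out 1 library gave 24 (without control replicate 4) to 1334 (without Arhgef11Sglt2 replicate 1); the cause was not tested. Fewer than 1.5 times away were the stricter filter (380), the block for library number range (395), robust shrinkage (345), no variance trend (372), pseudocounts of 1 (392) and 10 (387), equal totals (327) and equal upper quartiles (354). Of the 19 lists, fry called 2 (cholesterol synthesis and B and plasma cell) and camera with an estimated correlation 0; leaving out 1 library, camera called 16 to 24 of the 50 lists, among them 13 (without Arhgef11Sglt2 replicate 1) to 19 of these 19. Of the 19, camera lost 5 with sample weights (early proximal tubule 0.495, cytokines 0.295, interferon 0.213, hypoxia 0.198, p53 0.162), 3 under the stricter filter (neutrophil 0.0715, interferon and p53 0.0582), 2 with the replicate block (ribosomal proteins 0.42, B and plasma cell 0.0545) and 1 with the range block (interferon 0.0625). Interferon and p53 were also lost with pseudocounts of 1 (0.0522 each) and 10 (0.0529 each) and with equal totals (0.0763 and 0.0506). Arhgef11 was never called: its log2 difference was 0.027 with sample weights and -0.10 to 0.079 with 1 library left out, highest without Arhgef11Sglt2 replicate 1. The median of the cytokine list turned from 0.078 to -0.017 without Arhgef11Sglt2 replicate 1. Other signs of named genes turned only in genes that were not called: Ccl2 was 0.031 with the replicate block and 0.0082 with equal totals, Scnn1a was -0.12 with that block, -0.0044 with the range block and -0.0053 with equal upper quartiles, and Slc9a3 was 0.00068 with sample weights. With 1 library left out, the log2 difference ranged from -0.21 to 0.14 for Ccl2, from -0.19 to 0.10 for Slc9a3, from -0.081 to 0.11 for Scnn1a, from -0.93 to 0.20 for Col1a1, from -0.97 to 0.24 for Col3a1, and from -0.020 to 1.02 for Ren1. The calls of named genes were often lost. The replicate block ended 36 of them. Leaving out 1 library ended 173 and added 27, counted over genes and omissions. Of 18 alternative settings, the call was lost in 12 for Slc34a1, 11 for Fgb, 10 for Cldn10 and for Cxcl1, 9 for Fgg and 1 for Slc22a28. For Retnlg it was lost in 10 of 17. The count models planned (the DESeq2 test, 3 other normalization factors and robust dispersion in the count model, and voom with weights) were not run because they need counts, the fit without a filter equals the one reported, and the Xist covariate was not run because Xist is not among the listed genes. Estimated depth of 33000000 to 59700000 reads limits low genes most. The median and the camera direction differed in sign for the complement, SRF and YAP, and urothelium lists, none of them called.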

Other observations

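The lists in this part were written only after the data were seen, so their tests describe these libraries and are not independent evidence. Genes that break down branched-chain amino acids were lower in 7 of 19 in limma over all genes, and 12 did not pass. All 19 had a negative difference on the deposited scale, the smallest that of Bckdha (-0.01). Acat1 was 1.62-fold, Pcca 1.64-fold, Dbt 1.51-fold and Mccc1 1.48-fold lower, with limma adjusted p of 0.0154, 0.0189, 0.0166 and 0.0172. The camera adjusted p was 2.94e-12, and the adjusted p was 0.0615 with an estimated correlation. Acute phase and STAT3 target genes were higher in 7 of 16, among them the fibrinogen chains, Cebpd (2.72-fold, limma adjusted p = 0.0168) and Stat3 itself (1.64-fold, limma adjusted p = 0.0467). That list had a camera adjusted p of 3.87e-11 (adjusted p = 0.0615 with an estimated correlation). PPAR alpha targets outside the fixed list were higher in 8 of 18, for example Vnn1 (2.24-fold), Acot2 (2.80-fold) and Acot1 (2.96-fold), and when adjusted over the list alone 13 were higher and 2 lower, Cd36 (0.60-fold) and Fabp3 (0.77-fold). This list had a camera adjusted p of 8.14e-08 (adjusted p = 0.109 with an estimated correlation).

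Carboxylesterase and N-acetyltransferase 8 family genes, which hold near-identical copies, were lower in 8 of 17, led by Nat8f6 (2.62-fold, limma adjusted p = 0.0167); camera gave an adjusted p of 9.65e-09 (adjusted p = 0.0615 with an estimated correlation). Immunoglobulin chain genes were lower in 18 of 151 and had a negative difference in 150, with a camera adjusted p of 8.37e-34 (adjusted p = 0.109 with an estimated correlation). Their reads are shared between similar segments, and control replicate 2 was near the Arhgef11Sglt2 libraries for Igkc. None of 10 glucocorticoid targets passed over all genes, although 9 had a positive difference (camera adjusted p = 0.000604; adjusted p = 0.109 with an estimated correlation). The serine and one-carbon synthesis list was not called (adjusted p = 0.927), while its member Psat1 was 2.01-fold higher (limma adjusted p = 0.0147).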
